A study of Homo sapiens with 6 samples.

How the data were processed

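RNA of 6 T98G cultures or aliquots, 3 labelled shControl and 3 labelled shSLC1A5, was measured by paired-end sequencing. Per the labels' protocols, total RNA was extracted with TRIzol, poly(A) RNA was captured on oligo(dT) beads, and libraries were read as pairs of 150 bases on an Illumina NovaSeq 6000. Per the submitters' processing notes, fastp, HISAT2 and StringTie were used, with no version or role given. The genome build, the annotation, the strand setting and the rule for reads that match several genes are not given in the sources used here. Genes that overlap or copy one another are therefore reported as uncertain.

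The authors deposited 1 table for the series, which per the file headers holds counts per gene for each of the 6 libraries. The headers do not say how the counts were made, and they were taken as raw counts. Per the file headers, the authors also gave FPKM, fragments normalized to gene length and library size, for the same libraries. Columns were matched to samples by the number in each title and by NC for the control and sh for the other group, and 0 columns with values per sample were left unmapped. The IDs of 34674 of the 35750 listed genes are in GENCODE 29, and 99.97% of these overlap the same gene on GRCh38, so coordinates are given on that build as the table states them.

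The design written before the data were examined foresaw limma on log2(FPKM + 1) for a table of FPKM and edgeR for one with raw counts. Since counts were present, edgeR 4.0.16 in R 4.3.3 was the main test, with TMM normalization, a model with group alone, quasi-likelihood F tests and Benjamini-Hochberg adjustment over all genes tested, with an adjusted p under 0.05 as the threshold. Genes with a mean of at least 1 FPKM over the 6 libraries were tested. The standard error of a log2 fold change was taken as its size divided by the square root of F. FPKM are given as mean ± SD over 3 libraries. Total counts ran from 59327548 to 70802167 per library. The biological coefficient of variation was 0.0982 over all tested genes. Over tested genes, pairs of libraries within a group differed by 9.84 to 16.7 times the variance that counting noise gives (chi-square per gene), so no pair held one library under both names.

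Gene lists were tested with camera of limma 3.58.1 on log2 CPM (counts scaled to library size) with a prior count of 2, a preset correlation of 0.01, and Benjamini-Hochberg adjustment over lists with at least 5 tested members. The same test was run with an estimated correlation, and fry, which asks whether the genes of a list move on balance one way, was also run. Of 955 list genes, 938 were found in the table. Terms with 10 to 500 tested genes were tested with Fisher's exact test, one-sided, for higher and lower genes apart, against tested genes that carry any term of the same kind.

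The genes named were fixed by a rule before the data were examined. It takes SLC1A5, the 10 largest rises and 10 largest falls among genes past the threshold with a gene symbol and groups that do not overlap, up to 4 members past the threshold per list, 2 members of the highest FPKM in lists with fewer than 2 such members, and 20 genes named in advance, of which 1 is not reported here. A gene symbol was taken, by a choice made after the table was read, to be a name that the table's description credits to HGNC. Other genes are said to be chosen after their values were seen.

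A correction for GC content and length was added after seeing the data. The GC content and length of the longest GENCODE 29 transcript, known for 99.7% of tested genes, were fitted to each library's deviations by loess with a span of 0.3, and the fitted values entered edgeR as offsets. DESeq2 1.42.0, limma on log2(FPKM + 1) and on log2(FPKM + 0.1), quantile normalization, median-of-ratios scaling, other filters and variance models, library weights, a replicate block and the omission of each library were run as alternatives. Limma on log2(FPKM + 1), the correction for GC content and length, protein-coding genes alone and edgeR's filterByExpr were added after seeing the data. Lists of markers of neutrophils, B cells and red cells and of RNAs without a poly(A) tail were also chosen after the data were seen. Genes with 0 counts in every library of a group are compared with a floor of 3 counts per library, which covers counting error alone.

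The steps were tested on simulated data for the shSLC1A5 against shControl comparison, with counts drawn for 11800 real genes from the real means, dispersions and library sizes and 200 genes changed. edgeR recovered 37.3% of genes changed by 0.25 on the log2 scale, 71.6% of those changed by 0.5 and 93.9% of those changed by 1, and called 17 of 11600 unchanged genes. A list lowered in the simulation was called with either correlation and 0 of 37 other lists were. Counts were drawn for each gene independently, so this cannot show how correlation between genes affects the list calls in the data. A simulated GC trend of the observed slope, with no gene changed, gave 1844 called genes and 2 called lists before the correction and 5 genes and 0 lists after it. This trend was a straight line with a Spearman correlation of 0.743, against 0.49 in the data, where the trend was curved. It therefore does not give the number of real calls due to the trend, nor show that the correction removes all of it. Figures were drawn with matplotlib 3.10.9.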

Results

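The data were gene expression profiles of T98G, a human glioblastoma cell line, made by sequencing poly(A)-selected RNA. The labels name 2 groups of 3 libraries each, shControl and shSLC1A5, the second with a short hairpin RNA against SLC1A5, and the series asks how depletion of SLC1A5 changes gene expression. SLC1A5 encodes a sodium-dependent transporter of neutral amino acids that carries glutamine into the cell. The shControl libraries held 63420773, 62858288 and 59327548 counts and the shSLC1A5 libraries 70802167, 67759692 and 66998312. Of 35750 genes listed, 11841 had a mean of at least 1 FPKM (fragments normalized to the length of the gene model and the size of the library) over the 6 libraries and were tested. No label says whether the 3 libraries of a group came from separate cultures, so p-values measure the spread between these libraries, which may be technical.

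SLC1A5 (ENSG00000105281, chromosome 19, 46774883 to 46788594, minus strand) was only slightly lower in the libraries labelled shSLC1A5. Its counts were 22682, 22395 and 21515 in shControl and 23334, 22251 and 22079 in shSLC1A5, which overlap before scaling to depth. Its FPKM was 95.8 ± 1.15 in shControl and 87.9 ± 0.407 in shSLC1A5 (SD, n = 3), with all 3 shSLC1A5 values below all 3 shControl values. The edgeR log2 fold change was -0.14 (SE 0.018, adjusted p = 1.93e-04 by edgeR quasi-likelihood with Benjamini-Hochberg adjustment), a level 9.02% lower with a 95% confidence interval of 5.77% to 12.2%. An exact two-sided permutation test of the FPKM values gave p = 0.1, the smallest value that 3 libraries against 3 allow. With the correction for GC content and length that was added after seeing the data, the log2 fold change was -0.34, or 20.9% lower. Because the targeted transcript moved so little, every direction below is that of the libraries labelled shSLC1A5 against those labelled shControl.

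**Figure D1:**
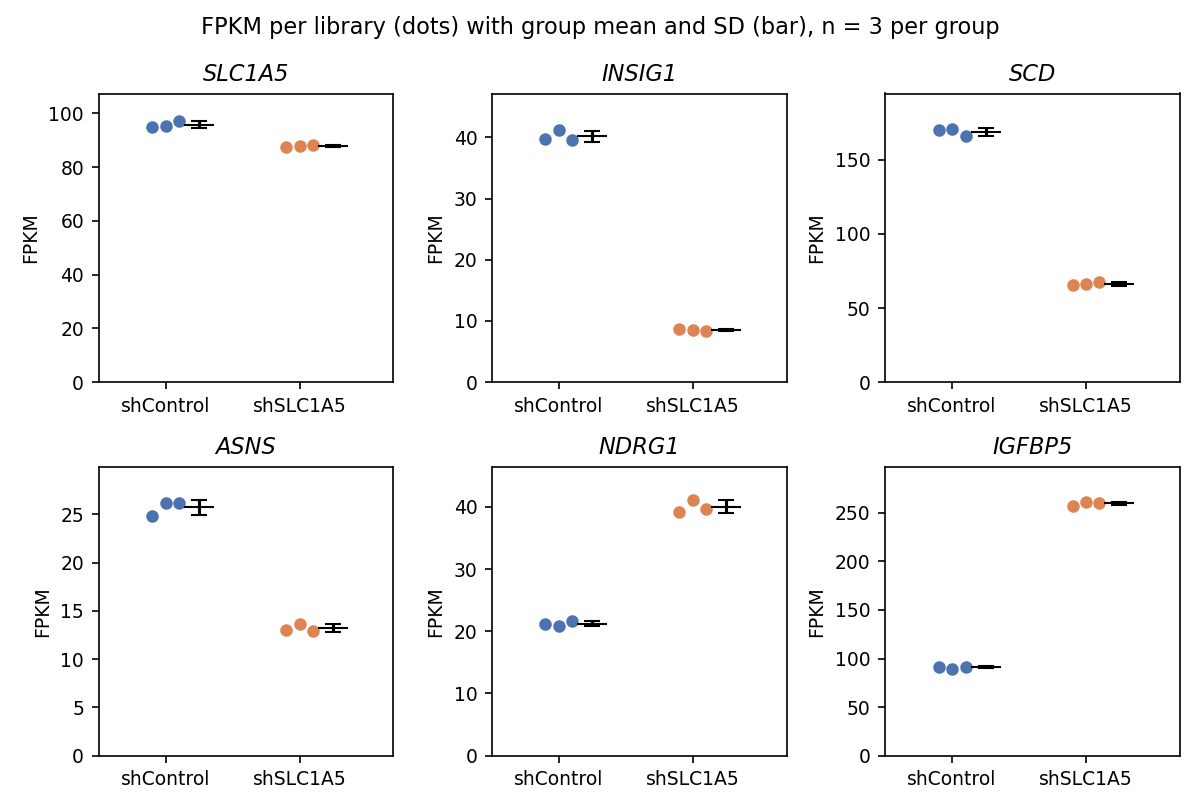
FPKM of SLC1A5, INSIG1, SCD, ASNS, NDRG1 and IGFBP5 in each library (dots, y axis from 0), with the mean and SD of 3 libraries per group (black bars). SLC1A5 fell from a mean of 95.8 to 87.9 FPKM, while INSIG1 fell from 40.2 to 8.50 and IGFBP5 rose from 91.0 to 259.6 FPKM.

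The libraries labelled shSLC1A5 had lower transcripts of cholesterol synthesis, the amino acid response, aminoacyl-tRNA synthetases and the unfolded protein response, and higher transcripts of glycolysis and the hypoxia response. Fatty acid synthesis was lower and extracellular matrix higher with the preset correlation between genes, each with an adjusted p = 0.0571 with an estimated correlation. INSIG1, which restrains sterol synthesis and is itself induced when sterol is low, fell from 40.2 ± 0.913 to 8.50 ± 0.210 FPKM (SD, n = 3). ASNS, which makes asparagine from aspartate and glutamine, fell from 25.7 ± 0.758 to 13.2 ± 0.424 FPKM. NDRG1, a gene induced by low oxygen, rose from 21.3 ± 0.429 to 40.0 ± 1.04 FPKM, and IGFBP5, a secreted binder of insulin-like growth factors, rose from 91.0 ± 1.14 to 259.6 ± 1.96 FPKM.

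In the edgeR test, 4641 genes differed at an adjusted p under 0.05, 2396 of them higher and 2245 lower. Most differences were small: 3085 of these genes (66.5%) had an absolute log2 fold change under 0.3, and 84 reached 1, with 57 higher and 27 lower. The 2 groups did not overlap in FPKM for 5870 of the 11841 tested genes, where chance gives 10% of genes. The fold changes rose with the GC content of the transcript (Spearman correlation across genes 0.49, genes not being independent replicates), and with the correction for GC content and length the count was 3054 genes, 1486 higher and 1568 lower, of which 2359 kept the call and direction of the uncorrected fit. Without shSLC1A5 replicate 1, whose reads include transcripts of other cell types as given with the markers of other cell types, 3982 genes, 15 lists and 324 terms passed. Replicates 2 and 3 also held such transcripts, such as IGHM with 378 and 688 counts against 0 in each shControl library. That fit therefore does not remove them.

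**Figure D2:**
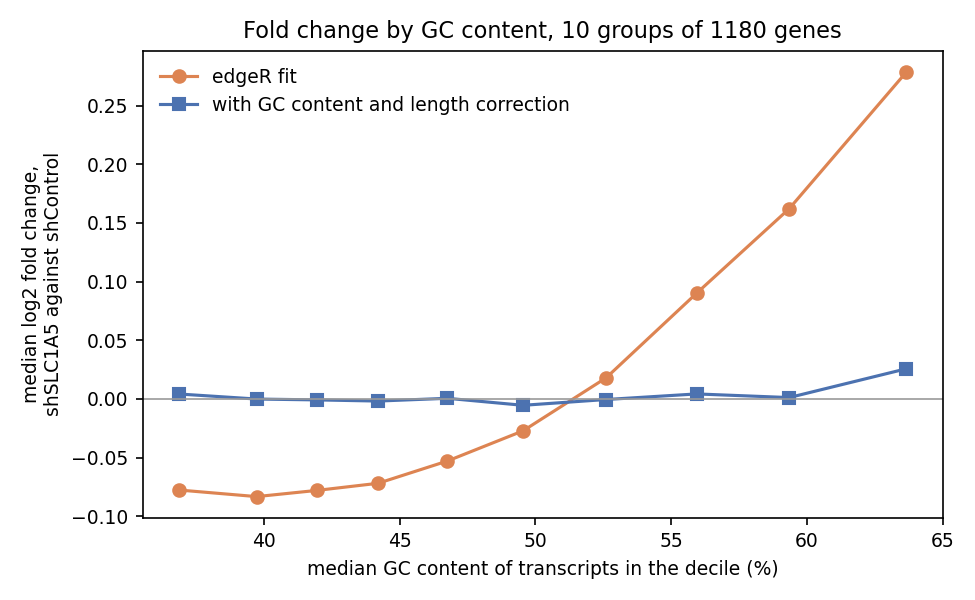
Median log2 fold change of shSLC1A5 against shControl (y axis) in 10 groups of 1180 genes ordered by GC content (x axis, median percent of each group), from the edgeR fit (circles) and with the correction for GC content and length (squares). The median went from -0.08 in the group lowest in GC to 0.28 in the highest, and lay at 0.03 or lower in every group after the correction.

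Of 43 gene lists fixed before the data were examined, 38 had at least 5 tested members and 15 were called by limma's camera (adjusted p under 0.05 over the 38 lists), 4 higher and 11 lower. With an estimated correlation between genes in place of the preset one, 6 of the 15 held: cholesterol synthesis, hypoxia response, glycolysis, aminoacyl-tRNA synthetases, unfolded protein response and amino acid response. After the correction for GC content and length 20 lists were called, among them 13 of the 15, and 11 of the 15 held with that correction and an estimated correlation. The 7 lists that the correction added to the calls were amino acid transporters, p53 target genes, MYC targets in ribosome biogenesis, immediate early genes and mesenchymal glioblastoma markers, all lower, and nuclear genes of oxidative phosphorylation and FOXO and insulin signalling, both higher, and 0 of these held with an estimated correlation.

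**Figure D3:**
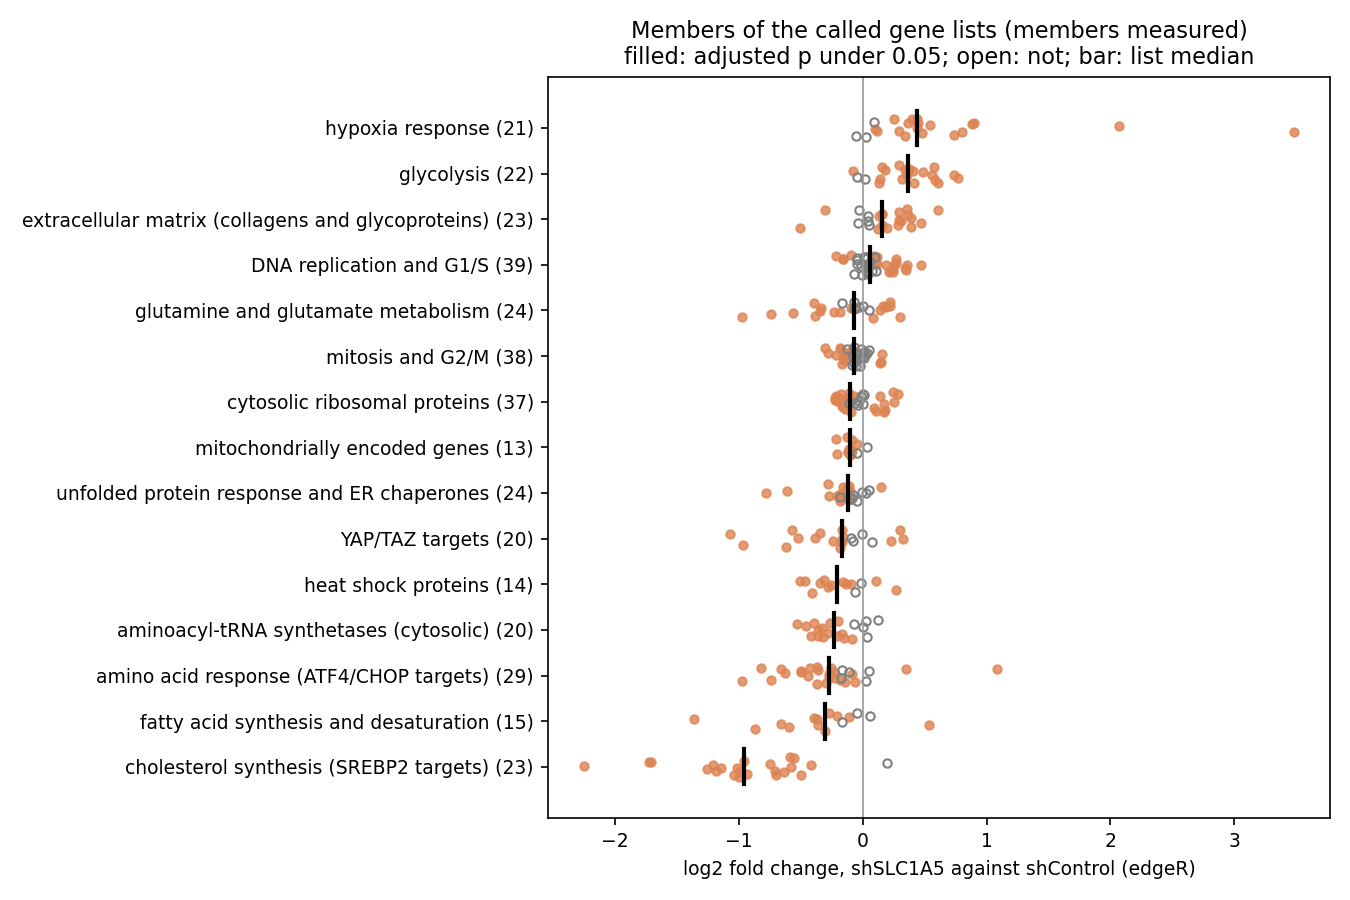
Log2 fold change of shSLC1A5 against shControl (x axis) of each tested member of the 15 called lists (y axis, members tested in brackets), filled where the gene's adjusted p was under 0.05 and open where not, with the list median as a bar. The medians ran from -0.96 for cholesterol synthesis to 0.44 for the hypoxia response.

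Cholesterol synthesis genes, targets of the transcription factor SREBP2, were the most strongly lowered list: 22 of 23 measured members fell and 0 rose (23 called when adjusted over the list alone), with a median log2 fold change of -0.96 (camera adjusted p = 1.15e-22). HMGCS1, the synthase that makes HMG-CoA, fell by 1.73 on the log2 scale (SE 0.039), from 18.6 to 5.68 FPKM, MSMO1 fell by 1.71 and IDI1 fell by 1.26. DHCR7, which catalyses a last step of the pathway, fell by 1.21, and STARD4, a sterol carrier, fell by 1.18. In fatty acid synthesis and desaturation, 11 of 15 members fell and 1 rose (13 called when adjusted over the list alone), with a camera adjusted p = 2.30e-08 and an adjusted p = 0.0571 with an estimated correlation. SCD, the stearoyl-CoA desaturase, fell from 169 ± 2.66 to 66.4 ± 1.27 FPKM (SD, n = 3), and the desaturases FADS2 and FADS1 fell by 0.87 and 0.66 on the log2 scale.

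Genes of the amino acid response, targets of ATF4 and CHOP, fell in 22 of 29 cases and rose in 2 (24 called when adjusted over the list alone; camera adjusted p = 2.30e-08). ASNS fell by 0.98 on the log2 scale (SE 0.035, adjusted p = 1.12e-08 by edgeR), CTH, which makes cysteine from cystathionine, fell by 0.82, and PSAT1, an enzyme of serine synthesis, fell by 0.74, from 102 to 61.5 FPKM. DDIT4, an inhibitor of mTORC1 that also responds to low oxygen, went the other way with a log2 fold change of 1.09. ATF4 itself fell by 0.18 and DDIT3, which encodes CHOP, fell by 0.37. Cytosolic aminoacyl-tRNA synthetases, which charge tRNAs, fell in 15 of 20 cases and rose in 0 (17 called when adjusted over the list alone; camera adjusted p = 8.03e-09), with GARS1 at -0.53, WARS1 at -0.46, MARS1 at -0.42 and TARS1 at -0.40 on the log2 scale.

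Amino acid transporters other than SLC1A5 were not called as a list (camera adjusted p = 0.131): 9 of 21 fell and 3 rose, with 12 called when adjusted over the list alone. The list was called lower after the correction for GC content and length (adjusted p = 0.0368, or adjusted p = 0.155 with an estimated correlation) and by fry (adjusted p = 5.18e-04), which asks another question. SLC1A4, the closest relative of SLC1A5, fell from 4.01 ± 0.129 to 2.62 ± 0.257 FPKM (SD, n = 3), SLC6A9, a glycine transporter, had a log2 fold change of -0.50, and SLC6A15 rose by 1.02. The glutamine transporter SLC38A1 fell by 0.33 and SLC38A2 fell by 0.14, or by 0.07 after the correction for GC content and length. SLC7A5, the leucine transporter, had a log2 fold change of -0.37, or -0.59 after the correction for GC content and length, and its partner SLC3A2 was at -0.06 (adjusted p = 0.0452 by edgeR, groups overlapping), or -0.16 after the correction (adjusted p = 1.50e-04). SLC7A11, the cystine transporter, was at -0.09 with overlapping groups. Its call was lost after the correction (adjusted p = 0.438) and without shControl replicate 1 (adjusted p = 0.0557), shSLC1A5 replicate 1 (0.0568) or shSLC1A5 replicate 3 (0.0528), and that of SLC3A2 was lost when any library other than shSLC1A5 replicate 2 was left out (adjusted p from 0.0509 to 0.174). SLC1A3, a glutamate transporter, was at -0.27 with an edgeR adjusted p of 0.107 and overlapping groups. SLC6A14 was below the expression minimum and was not tested.

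Glutamine and glutamate metabolism was called lower with 10 of 24 members lower and 7 higher (19 called when adjusted over the list alone), a median log2 fold change of -0.07, a camera adjusted p = 0.0193 and an adjusted p = 0.154 with an estimated correlation. The call was also lost with a mean FPKM of at least 5 (adjusted p = 0.0726) and with quantile normalization (adjusted p = 0.0774). Its largest falls, ASNS and PSAT1, are also in the amino acid response list. IDH1, an isocitrate dehydrogenase, fell by 0.56 and GLUD1, glutamate dehydrogenase, fell by 0.23 on the log2 scale. GLUL, glutamine synthetase, rose by 0.22. The lists of glutathione and NRF2 targets and of ferroptosis regulators were not called (camera adjusted p = 0.204 and 0.423): 13 of 26 and 8 of 24 members rose, 8 and 5 fell, and 22 and 13 were called when adjusted over the list alone. HMOX1, heme oxygenase, fell by 0.67 and AKR1B10 rose by 0.27. GPX4, which removes lipid peroxides, had a log2 fold change of 0.23, or 0.05 with the call lost (adjusted p = 0.347 by edgeR) after the correction for GC content and length.

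Hypoxia response genes rose in 18 of 21 cases and fell in 0 (18 called when adjusted over the list alone; camera adjusted p = 1.16e-12). ANGPTL4, a secreted inhibitor of lipoprotein lipase, rose from 0.380 ± 0.0223 to 4.35 ± 0.346 FPKM (SD, n = 3), CA9, a carbonic anhydrase, from 0.805 ± 0.170 to 3.44 ± 0.622, and ADM, adrenomedullin, from 35.3 to 65.5 FPKM. Glycolysis genes rose in 19 of 22 cases and fell in 1 (20 called when adjusted over the list alone; camera adjusted p = 2.99e-14). ENO2, an enolase, rose by 0.74 on the log2 scale, PFKFB3 by 0.61 and HK2, a hexokinase, by 0.58. SLC16A3, which exports lactate, rose by 0.77, or by 0.51 after the correction for GC content and length. TXNIP, which limits glucose uptake, rose from 12.8 to 17.9 FPKM.

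Extracellular matrix genes rose in 16 of 23 cases and fell in 2 (18 called when adjusted over the list alone), with a camera adjusted p = 2.75e-06 and an adjusted p = 0.0571 with an estimated correlation. LAMA4, a laminin chain, rose by 0.47 on the log2 scale, and the collagen cross-linking enzymes LOXL1 and LOXL2 rose by 0.61 and 0.39, or by 0.27 and 0.24 after the correction for GC content and length. THBS1, thrombospondin, fell by 0.51. Targets of the transcriptional regulators YAP and TAZ fell in 13 of 20 cases and rose in 3 (16 called when adjusted over the list alone), with a camera adjusted p = 1.75e-04 and an adjusted p = 0.144 with an estimated correlation. Among them the matricellular genes CCN1 and CCN2 fell from 151 ± 4.14 to 78.2 ± 2.89 and from 47.6 ± 2.76 to 22.8 ± 0.452 FPKM (SD, n = 3).

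Genes of the unfolded protein response and chaperones of the endoplasmic reticulum fell in 15 of 24 cases and rose in 1 (18 called when adjusted over the list alone; camera adjusted p = 1.23e-06). DNAJB9 fell by 0.78 on the log2 scale, HERPUD1 fell by 0.61, and XBP1, a transcription factor of this response, fell by 0.28. Heat shock proteins fell in 10 of 14 cases and rose in 2 (12 called when adjusted over the list alone), with a camera adjusted p = 1.14e-05 and an adjusted p = 0.138 with an estimated correlation. HSPA8, the constitutive HSP70, fell from 408 ± 0.983 to 324 ± 4.81 FPKM (SD, n = 3). HSPA1A and HSPA1B were at -0.46 and -0.51 on the log2 scale, but they are nearly identical copies and their separate counts are uncertain. Cytosolic ribosomal proteins went both ways, with 20 of 37 lower and 9 higher (29 called when adjusted over the list alone), a camera adjusted p = 0.0227 and an adjusted p = 0.613 with an estimated correlation. That call was lost without shControl replicate 3 (adjusted p = 0.0767) and without shSLC1A5 replicate 3 (adjusted p = 0.0539), with quantile normalization (adjusted p = 0.361), with a mean FPKM of at least 5 (adjusted p = 0.114) and with fry (adjusted p = 0.0934).

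DNA replication and G1/S genes were called higher, with 16 of 39 higher and 4 lower (21 called when adjusted over the list alone), a median log2 fold change of 0.06, a camera adjusted p = 0.00483 and an adjusted p = 0.0795 with an estimated correlation. E2F2 rose by 0.47 on the log2 scale and MCM2, part of the replicative helicase, by 0.36, or by 0.32 and 0.22 after the correction for GC content and length. CDT1, at 0.35, and POLD1, at 0.34, lost their calls with that correction (0.06 and 0.05). Mitosis and G2/M genes were called lower, with 15 of 38 lower and 3 higher (19 called when adjusted over the list alone), a camera adjusted p = 0.00173 and an adjusted p = 0.0655 with an estimated correlation. The kinase TTK fell by 0.30 on the log2 scale. The list's median of -0.07 became -0.02 after the correction and its call was lost (adjusted p = 0.222), as it was with quantile normalization (adjusted p = 0.0711). MKI67, a proliferation marker, was at 48.0 ± 1.60 and 45.9 ± 0.788 FPKM (SD, n = 3) with an edgeR adjusted p of 0.0284 and overlapping groups, CCND1 at 83.1 and 82.9 FPKM, and MYC at 11.1 and 12.5 FPKM with an adjusted p of 0.0459. After the correction for GC content and length, the adjusted p was 0.0755 for MKI67 and 0.125 for MYC, and both calls were lost. MKI67 also lost its call without shControl replicate 1 or 2 or shSLC1A5 replicate 1 or 3 (adjusted p from 0.0643 to 0.104), and MYC without shControl replicate 2 or 3 or shSLC1A5 replicate 3 (adjusted p from 0.0779 to 0.151).

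Mitochondrially encoded genes were called lower, with 11 of 13 lower and 0 higher (11 called when adjusted over the list alone), a median log2 fold change of -0.10, a camera adjusted p = 5.19e-05 and an adjusted p = 0.188 with an estimated correlation. MT-ND1, a subunit of complex I, fell by 0.22 on the log2 scale, or by 0.14 after the correction for GC content and length. With that correction the median of the list was 0.01 and the call was lost (adjusted p = 0.974), and with quantile normalization the median was 0 (adjusted p = 0.799) and MT-ND1 was at -0.06 (adjusted p = 0.356). Quantile normalization gives equal ranks equal values, so it may remove a difference among very abundant transcripts, which was not tested. These transcripts made up 4.20%, 4.20% and 4.17% of counts in shControl and 3.90%, 3.80% and 3.92% in shSLC1A5. Nuclear genes of oxidative phosphorylation were not called (camera adjusted p = 0.541), with 11 of 36 higher, 6 lower and 17 called when adjusted over the list alone. After the correction for GC content and length they were called higher (adjusted p = 0.0439, or adjusted p = 0.155 with an estimated correlation).

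Among the 10 largest rises taken by the naming rule, ANGPTL4 and CA9 belong to the hypoxia response, and MIR210, a microRNA gene whose reads overlap those of its host transcript, rose by 2.24 on the log2 scale. The imprinted noncoding RNA H19 rose from 0.361 ± 0.0621 to 1.67 ± 0.0330 FPKM (SD, n = 3). IGHM, IGKV3-20 and IGKC are immunoglobulin genes, which a glioma cell line does not normally express. IGHM had counts of 0 in each shControl library and of 729, 378 and 688 in shSLC1A5, at least 110-fold higher than a floor of 3 counts per library. For IGKV3-20 the bound was at least 26.9-fold. CCL15-CCL14 and GATD3B overlap or nearly copy other genes and are uncertain. SCARNA10 was at 2.93 on the log2 scale through shSLC1A5 replicate 1 and at 0.44 without it (adjusted p = 0.546 by edgeR), and its call was also lost without any one of the shControl libraries. CCL15-CCL14 lost its call without shControl replicate 3 (adjusted p = 0.104) and without shSLC1A5 replicate 2 (adjusted p = 0.0781). Of the 10 largest falls, 7 were the lipid genes INSIG1, HMGCS1, MSMO1, SCD, IDI1, DHCR7 and STARD4. The others, DHFRP1, RNU6-850P and USP32P2, are pseudogenes whose reads may belong to related genes. RNU6-850P lost its call without shSLC1A5 replicate 1 (adjusted p = 0.0884), and USP32P2 without it (adjusted p = 0.0543) and without shControl replicate 3 (adjusted p = 0.0776). With DESeq2, CCL15-CCL14 (adjusted p = 0.219), RNU6-850P (0.108) and USP32P2 (0.0626) also lost their calls. With edgeR and no filter on low values, the same genes, SCARNA10 and MIR210 (adjusted p = 0.0657) did.

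Markers of other cell types, which T98G cells should largely lack, were summed per library as counts scaled to library size (CPM). The 16 immune genes reached 28.1 in shSLC1A5 replicate 1, 9.03 and 8.72 in replicates 2 and 3, and 6.43, 7.33 and 6.57 in shControl. The 10 endothelial genes were at 37.1, 36.5 and 34.2 in shSLC1A5 against 24.0, 23.6 and 21.7 in shControl. EGFL7 among them rose by 0.92 on the log2 scale, or by 0.58 after the correction for GC content and length. PECAM1, VWF, CDH5 and KDR were also above every shControl library, but ROBO4, TIE1, ESAM, TEK and CLDN5 overlapped between the groups. ROBO4 was at 11.26, 9.784 and 10.62 CPM in shControl and 10.8, 9.696 and 9.239 in shSLC1A5. Genes other than EGFL7 were named here after their values were seen. The 13 epithelial genes lay between 105 and 115 in all 6 libraries, but KRT18 alone gave 89.7 to 105 of this. That sum therefore says little about the other epithelial genes. KRT8 was at 6.433, 8.288 and 7.585 CPM in shControl and 9.632, 11.48 and 10 in shSLC1A5. CDH1, chosen after its values were seen, had 4, 0 and 0 counts in shControl and 55, 20 and 53 in shSLC1A5. EPCAM and CLDN7 overlapped between the groups.

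**Figure D4:**
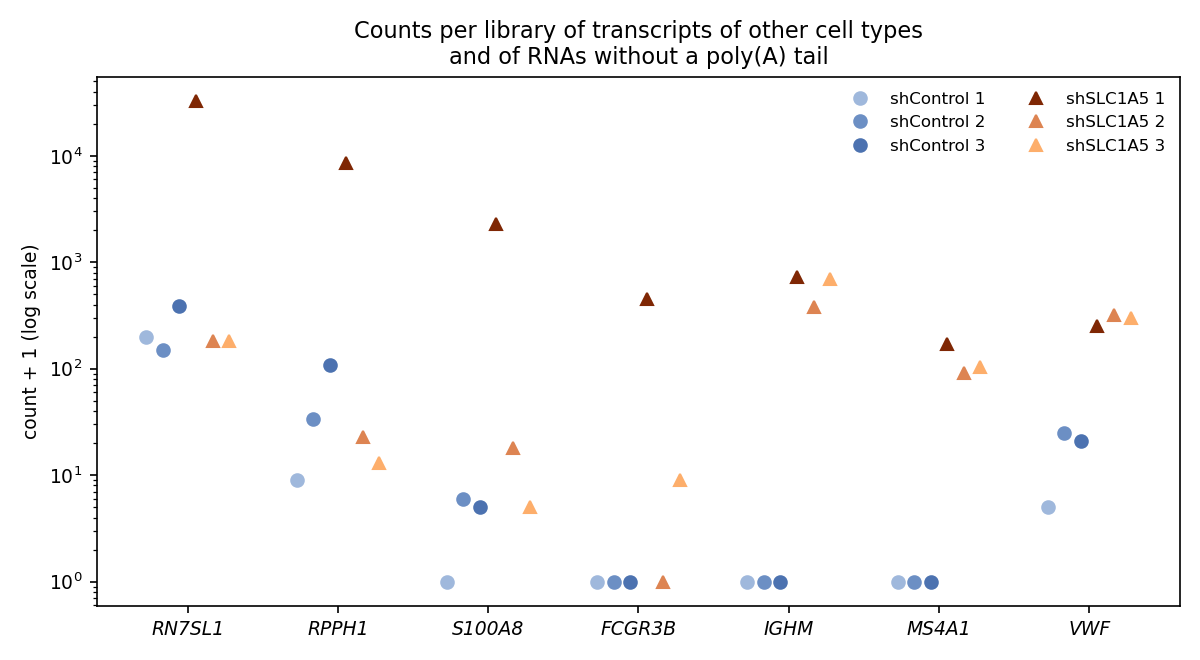
Counts per library (y axis, count + 1 on a log scale) of RN7SL1 and RPPH1, RNAs without a poly(A) tail, and of genes of other cell types chosen after their values were seen, in shControl (circles) and shSLC1A5 (triangles). S100A8 had 2301 counts in shSLC1A5 replicate 1 and at most 17 elsewhere, while MS4A1 had 168, 90 and 102 counts in shSLC1A5 and 0 in each shControl library.

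The GO, KEGG and Reactome terms that the authors' table gives for each gene were tested with Fisher's exact test, one-sided, and 295 terms passed after Benjamini-Hochberg adjustment. Among the higher genes, collagen-containing extracellular matrix held 72 of 142 tested genes where 31.0 were expected (adjusted p = 3.54e-11), canonical glycolysis 16 of 18 where 3.93 were expected (adjusted p = 1.40e-06) and the HIF-1 signaling pathway 32 of 75 where 16.8 were expected (adjusted p = 0.00572). Among the lower genes, translation held 128 of 301 where 61.6 were expected (adjusted p = 2.97e-15), focal adhesion 130 of 345 where 70.6 were expected (adjusted p = 6.08e-11), protein processing in endoplasmic reticulum 63 of 141 where 34.0 were expected (adjusted p = 2.38e-05) and sterol biosynthetic process 18 of 25 where 5.12 were expected (adjusted p = 1.46e-05). With the correction for GC content and length, 166 of the 295 terms also passed, among them the 7 named here, which were chosen after their values were seen. Fisher's exact test treats genes as independent, which genes of one pathway are not.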

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

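All tests and marker lists in this part were chosen after the results were seen.

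In shSLC1A5 replicate 1, 20 neutrophil genes summed to 124 CPM (counts scaled to library size), against 5.49, 4.58 and 4.37 in shControl, a signal outside the gene lists fixed beforehand that lies above the control libraries. S100A8, the most abundant, had 2301 counts there and at most 17 in any other library, and FCGR3B had 453 against at most 8. In shControl, 2 of the 20 genes had a mean of at least 1 CPM, and 0 of them are in the immune marker list fixed beforehand. The red cell genes, 7 of them measured, summed to 15.8 CPM in the same library and to at most 0.295 in the others.

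Expression of neutrophil genes brought on by SLC1A5 depletion would reach all 3 libraries, but replicates 2 and 3 summed to 6.04 and 8.34 CPM, far under replicate 1. Reads of whole blood RNA with its globin transcripts stay open: the alpha globin genes HBA1 and HBA2 had 0 counts in replicate 1, beside 773 of ALAS2, and 9 and 11 in replicate 2, but they are nearly identical copies whose shared reads may not have been counted. The 5 RNAs listed as lacking a poly(A) tail (RN7SL1, RN7SL2, RN7SK, RPPH1 and RMRP) summed to 944 CPM in replicate 1, 52.3 times the highest other library, which is consistent with reads of a leukocyte library made without poly(A) selection. The oligo(dT) capture in the labels would deplete such RNAs in the cells' own library, though the other libraries still held RN7SL1 at 150 to 389 counts. The excess of these RNAs alone therefore does not show a leukocyte source, and a weaker capture in replicate 1 was not tested. The hypothesis is that the reads of other cells entered during or after library preparation. Whether they came through a shared sequencing run stays open, because no run is given in the labels.

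A B cell signal lay above the control libraries in all 3 shSLC1A5 libraries: 17 B cell genes summed to 40.7, 30.4 and 33.0 CPM in replicates 1, 2 and 3, against 14.8, 16.5 and 16.4 in shControl. The excess was in 14 of the 17 genes in every shSLC1A5 library, among them MS4A1 with 168, 90 and 102 counts against 0 in each shControl library, while 2 of the 17 had a mean of at least 1 CPM in shControl and 3 are also in the immune list.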

How the results depend on the processing

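Limma on log2(FPKM + 1), the correction for GC content and length, protein-coding genes alone and filterByExpr were chosen after seeing the data, and the other alternatives before. SLC1A5 stayed lower and past the threshold under every alternative run, with log2 fold changes from -0.34 to -0.10. Leaving out each library gave 3863 to 4081 genes, 14 to 17 lists, 240 to 341 terms and SLC1A5 at -0.14 to -0.13. DESeq2 called 5002 genes, with 19 adjusted p missing, and limma on log2(FPKM + 1) called 4132, of which 3906 were shared with the main test in the same direction. The correction for GC content and length gave 3054 genes, 1486 of them higher, and kept 2359 of the 4641. An absolute log2 fold change of at least 1 left 84 genes, 57 higher and 27 lower, by construction. Camera with an estimated correlation called 6 lists and fry, which tests another hypothesis, 29. The terms called numbered 503 with no filter, 456 with filterByExpr, 156 with a mean FPKM of at least 5 and 183 with quantile normalization. The first 3 change which genes are tested, and for quantile normalization the cause was not tested.

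CCND1, not past the threshold anywhere, turned from -0.02 to 0.0018 with a mean FPKM of at least 5, 0.013 with quantile normalization and lay between -0.0289 and 0.0055 over the fits without 1 library. With quantile normalization MT-CO1 was at 0.0065, MT-ND5 at 0.027 and the mitochondrially encoded list at a median of 0, and the cause was not tested. With the correction for GC content and length that list had a median of 0.011. The variance alternatives planned for limma were run in edgeR's fit.

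No pairing by replicate number was seen: deviations from the group means correlated at -0.15, 0.04 and -0.03 for numbers 1, 2 and 3. Not every library correlated best with its own number. A culture or day shared by a number stays possible, as no label gives one. With the replicate number as a block, 4470 genes (2311 higher, 2159 lower), 15 lists and 345 terms were called and SLC1A5 was at -0.14.

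The simulation recovered 37.3% of changes of 0.25 on the log2 scale. It changed a far smaller share of genes than the 4641 called here, which makes the adjusted threshold stricter. That share of recovered genes therefore does not carry over to these data.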

Other observations

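The tests that weigh explanations, those of other splits of the libraries, the correction for GC content and length and the fit with filterByExpr were chosen after the results were seen.

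In the FOXO and insulin signalling list, 5 of 13 members rose and 2 fell, with 7 called when adjusted over the list alone (camera adjusted p = 0.0942). That list passed without shControl replicate 2 (adjusted p = 0.0495), with no filter (0.00255), a mean FPKM of at least 5 (7.97e-04), filterByExpr (0.00663) and the correction for GC content and length (0.0117). It did not pass with an estimated correlation (adjusted p = 0.341, or 0.227 with the correction as well). IGFBP5 and IGFBP3, binders of insulin-like growth factors, rose by 1.50 and 0.65 on the log2 scale, while IRS2, an insulin receptor substrate, fell by 0.79 and the ubiquitin ligase subunit FBXO32 fell by 0.52. Among NF-kB targets and cytokines, 5 of 20 rose and 6 fell, with 12 called when adjusted over the list alone (camera adjusted p = 0.781). CSF1, a growth factor of macrophages, rose from 62.2 ± 1.01 to 92.1 ± 0.942 FPKM (SD, n = 3) and PTGS2, a cyclooxygenase, from 5.04 to 7.82, while CXCL8 fell from 77.8 ± 2.76 to 55.6 ± 2.01 and IL11 from 2.05 to 1.21 FPKM. In the ERK output list 2 of 18 rose and 4 fell, with 6 called when adjusted over the list alone: SPRY1 rose by 0.71 and its relative SPRY2 fell by 0.67, with DUSP6 at -0.47 (camera adjusted p = 0.565 for the list).

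The fall of SLC1A5 mRNA was 9.02%, small for a knockdown. A GC trend that hides a fall by more than 1 on the log2 scale is argued against by the corrected log2 fold change of -0.34 (SE 0.019). An exchange of a pair of libraries between the groups is argued against by 0 libraries lying on the other group's side of the first principal component. Incomplete knockdown, loss of the hairpin from part of the cells, or an effect on protein alone stay open, as protein was not analysed here.

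Fold changes rose with the GC content of the transcript, with a Spearman correlation of 0.49 across genes. A difference in total count is argued against, since the correlation was 0.489 after all libraries were thinned to the shallowest. A preparation or sequencing batch that coincides with the groups cannot be told apart from an effect of the hairpin on this trend. The lowest correlation among the shSLC1A5 libraries was 0.453, while the shControl libraries lay between -0.029 and 0.033, and no label gives a batch. Transcripts of other cell types also followed the groups: 14 of 17 B cell genes were above every shControl library in all shSLC1A5 libraries. Whether a batch explains both patterns was not tested. The trend as the whole cause of the list calls is argued against by the 13 lists that kept their call and direction after the correction. Among them, cytosolic ribosomal proteins (camera adjusted p = 0.265) and glutamine and glutamate metabolism (adjusted p = 0.110) did not pass with that correction and an estimated correlation. They also did not pass with an estimated correlation before the correction (adjusted p = 0.613 and 0.154). The call itself is therefore uncertain for these 2, and no conclusion on the trend is drawn for them. For the mitochondrially encoded list, whose median went from -0.10 to 0.011, and the mitosis list, from -0.074 to -0.016, the trend may be the whole cause.

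Other splits of the 6 libraries into 3 and 3 number 10 with the real one, too few for a share under 0.05. The real split gave the highest count in 1 of the 10 for genes (4641, highest other 1), lists (15, highest other 9) and terms (295, highest other 0). The other splits called 5 to 9 lists each. Every one of them mixes the groups unevenly and so keeps part of the difference between them, which is why these counts give no chance level.

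Some values stood out and were chosen after they were seen. PDCD6-AHRR, a readthrough gene, had 0 counts in the 3 shControl libraries and in shSLC1A5 replicate 1 and 1737 and 1795 counts in shSLC1A5 replicates 2 and 3. It overlaps PDCD6, which had 3904 to 5586 counts in every library, and AHRR, so its counts are uncertain. Whether the pattern comes from how reads were assigned was not tested. CDH5 and VWF, endothelial genes, had 118, 100 and 98 and 250, 317 and 299 counts in shSLC1A5, against 0 in each and 4, 24 and 20 in shControl.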
